A study of Mus musculus with 9 samples.

How the data were processed

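Mouse bone marrow mesenchymal stem cells, bought as a commercial stock, were cultured for 7 days under 3 conditions, per the labels. These were proliferation medium (PM), osteogenic medium (OM), which adds ascorbic acid at 0.2 mM, beta-glycerophosphate at 10 mM and dexamethasone, a synthetic glucocorticoid, at 100 nM, and osteogenic medium with dicalcium silicate, a calcium silicate ceramic abbreviated C2S. Each condition had 3 libraries of total RNA, extracted with TRIzol and prepared by a standard Illumina protocol, per the labels' protocols. The labels list several C2S doses and do not tie one to the sequenced samples, so no dose is given. They also do not say whether the 3 libraries of a condition came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

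Each library came with a table of circular RNAs and a table of linear genes. The submitters' processing notes name STAR, HTSeq and RSEM and the genome build mm10, without roles or versions. In the files, all 6614 listed circRNAs carried an identifier from CIRI and one from find_circ. The circRNA values deposited by the authors were taken as RPM, back-splice junction reads scaled to a fixed total of circRNA reads per library, since each of them was a whole multiple of 1 step per library within a tolerance of 0.001 reads. The smallest multiple was 2 reads, so an entry without a value can stand for 0 or 1 read, or for a junction that was not called, and it was set to 0. Of 2461 entries of tested circRNAs whose group had at least 10 reads in each of its other 2 libraries, 34 (1.38%) had no value, in 29 circRNAs, of which 21 had ends in 2 genes. A group with 2 unlisted libraries does not enter this count. The linear values deposited by the authors were taken as FPKM, fragments scaled to transcript length and library total. The headers name no unit, and value times transcript length fell on whole reads for 98.2% to 98.5% of the low values of each library within a tolerance of 0.1 reads. The longest GENCODE M21 transcript of each gene served as its length, and 30814 of 31405 linear entries matched that annotation, which is on the same build. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. A further 26 gene symbols were held as dates by a spreadsheet and were replaced with the annotation's symbol for the same Ensembl identifier.

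The recovered steps gave 29581760 to 38763946 reads behind the linear values and 13691 to 20769 circRNA reads per library. The listed circRNAs held 90.6% to 93.0% of those reads, with a median of 3 reads per listed circRNA, so single circRNAs rest on few reads. Simulated data were drawn from the means and depths of all 9 libraries, with 200 features above a minimum of mean reads changed in C2S. In C2S against OM limma recovered 89.6% of linear genes changed 1.5-fold and 100% of those changed 2-fold. Among 12633 genes tested there were 6 false calls, 3.03% of all calls. Among 2245 simulated circRNAs of the same comparison it recovered 44.8% of 2-fold, 91.0% of 4-fold and 95.5% of 8-fold changes. These simulated libraries held only counting error and a dispersion. It was 0.00297 for linear genes, fitted to the real libraries, and 0.001 for circRNAs, a preset minimum. Real recovery of circRNAs may therefore be lower.

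Designs, gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. They named a count test as the main test and, where files hold only normalized values, limma on log values, which was therefore used here. Linear genes with FPKM of at least 1 in at least 3 libraries (13049 genes) were tested on log2(FPKM + 1). The 2898 circRNAs listed in at least 3 libraries were tested on log2(RPM + 111.7), the pseudocount being the median over libraries of the smallest value above 0. Fold changes are on these scales, which understate the change of low genes. All 9 libraries entered 1 limma fit (version 3.58.1, R 4.3.3, empirical Bayes with a mean trend, 6 residual degrees of freedom before moderation), with the group as the only factor and Benjamini-Hochberg adjustment per comparison at 0.05. Every adjusted p printed comes from limma, apart from those of the exact permutation tests, and every ± after a log2 fold change is its standard error. The comparisons were OM with PM, C2S with OM and C2S with PM.

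The 25 lists with 631 gene entries, also fixed beforehand, were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The 21 lists with at least 5 tested genes covered osteoblast, adipocyte and stromal genes, the glucocorticoid, interferon, inflammatory, unfolded protein and oxidative stress responses, cell cycle, ribosomal proteins, mitochondrial mRNAs, extracellular matrix, matrix proteases, contractile genes, cholesterol synthesis, glycolysis and hypoxia, the Wnt and BMP/TGF-beta pathways, calcium and phosphate handling, circRNA biogenesis and decay factors, and lysosome and autophagy. The macrophage, endothelial, chondrocyte and blood cell lists had fewer tested genes and are given by their members. The rule named, per comparison, the 8 largest rises and 8 largest falls past the threshold among annotated protein-coding or lncRNA genes with a mean FPKM of at least 1 and no overlap between the groups. It also named up to 4 members with the smallest p of each list with a call, Gas7, the 6 largest circRNA rises and falls (or, with too few calls, those with the smallest p), circ_1983 and circRNAs of Gas7. With 3 against 3 libraries, chance leaves 10% of genes without overlap.

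The circRNA change relative to the host gene was the limma test of log2(RPM + 111.7) minus log2(FPKM + 1), in place of a ratio of CPM values fixed beforehand. It covered 2690 circRNAs in 1571 host genes. Pearson correlations between circRNA and host changes were taken across circRNAs, with a spread from 200 bootstrap draws over host genes. Comparisons sharing libraries were set beside 100 simulations of unchanged groups, or 20 for overlaps of calls. Total circRNA reads per 1000000 linear reads, and circRNAs detected after thinning each library to 12401 circRNA reads (mean of 50 draws), were compared by two-sided exact permutation tests of group means, whose smallest p with 3 against 3 is 0.1. Coordinates are 1-based on mm10. Sequence similarity was measured with blastn 2.17.0 on GENCODE M21 transcripts. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

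The alternatives were median-of-ratios scaling, no low-value filter, filters of 30 linear or 10 circRNA reads in at least 3 libraries, a pseudocount of 0.1 for FPKM or 4 times larger for RPM, only the 6 libraries compared, a fold of at least 2, the replicate number as a block, circRNA reads scaled by linear reads, and each library left out in turn. Limma's voom on the recovered reads, a test without circRNAs whose ends lie in 2 genes, and a test without the 29 circRNAs with unlisted entries beside many reads, were added after the data had been seen. So were the covariance as the value of the comparison between fold changes, the spreads used for it and for the circRNA and host correlations, and the divisor of 5 for the smaller pseudocount of the host-relative test. A planned test with a negative binomial count model was not run, although reads could be recovered from the normalized values. MicroRNA levels, and so miR-6931 of the series title, were not analysed here. Not every gene named by the rule is printed, and the others enter by the counts of their lists. Some further genes are not reported here.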

Results

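RNA was sequenced from mouse bone marrow mesenchymal stem cells, the stromal cells of the marrow that can form bone, after 7 days in PM, in OM or in OM with C2S. Each group had 3 libraries, and every group value below is a mean ± SD with n = 3. The linear values rested on 29581760 to 38763946 reads per library and the circRNA values on 13691 to 20769 back-splice junction reads. On the first principal component of the linear genes, which held 71.0% of the variance, the PM libraries lay between -41.3 and -40.5 and the OM and C2S libraries between 17.2 and 22.4. The second component, with 10.9%, placed the OM libraries between -15.2 and -12.2 and the C2S libraries between 11.5 and 14.2. Pearson correlations between libraries across genes ranged from 0.988 to 0.995 within groups, from 0.982 to 0.988 between OM and C2S and from 0.941 to 0.951 between PM and the others. The 7SK RNA gene Rn7sk held 28.8% to 36.1% of the summed FPKM of a library.

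The comparison of OM with PM asked what the osteogenic supplements changed. Fkbp5, a glucocorticoid-induced co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, positions 28399094 to 28517527), rose from 7.10 ± 0.289 FPKM in PM to 218 ± 7.57 in OM, a log2 fold change of 4.76 ± 0.043 (limma adjusted p = 2.9e-11). The haptoglobin gene Hp rose from 0.699 ± 0.0510 to 45.7 ± 3.15 FPKM, the metallothionein Mt2 from 42.3 ± 4.66 to 956 ± 40.7, and Tsc22d3, which encodes a glucocorticoid-induced leucine zipper protein, from 23.2 ± 1.90 to 509 ± 19.8. Sult1a1 (5.93 ± 0.068) showed the highest log2 rise of the named genes, although its reads may be shared with the near-identical Gm6939, and Dpep1 (4.54 ± 0.052), Ndrg2 (4.50 ± 0.055) and Igfbp3 (4.43 ± 0.063) rose as well. The chemokine Ccl8 fell from 40.0 ± 7.62 to 0.837 ± 0.227 FPKM, the Wnt antagonist Dkk2 from 137 ± 10.3 to 9.37 ± 0.394, and the growth factor Igf1 from 17.0 ± 1.09 to 0.799 ± 0.0440. Further falls, as log2 fold changes, were those of Qpct (-4.00 ± 0.11), Syt13 (-3.87 ± 0.075), the secretogranin Scg2 (-3.70 ± 0.076), the proenkephalin gene Penk (-3.30 ± 0.089) and the oxytocin receptor Oxtr (-3.19 ± 0.064). By limma, 7151 of 13049 genes passed, 3542 higher and 3609 lower in OM, with a median absolute log2 change of 0.39 among them. A fold of at least 2 was met by 445 of the rises and 331 of the falls.

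**Figure D1:**
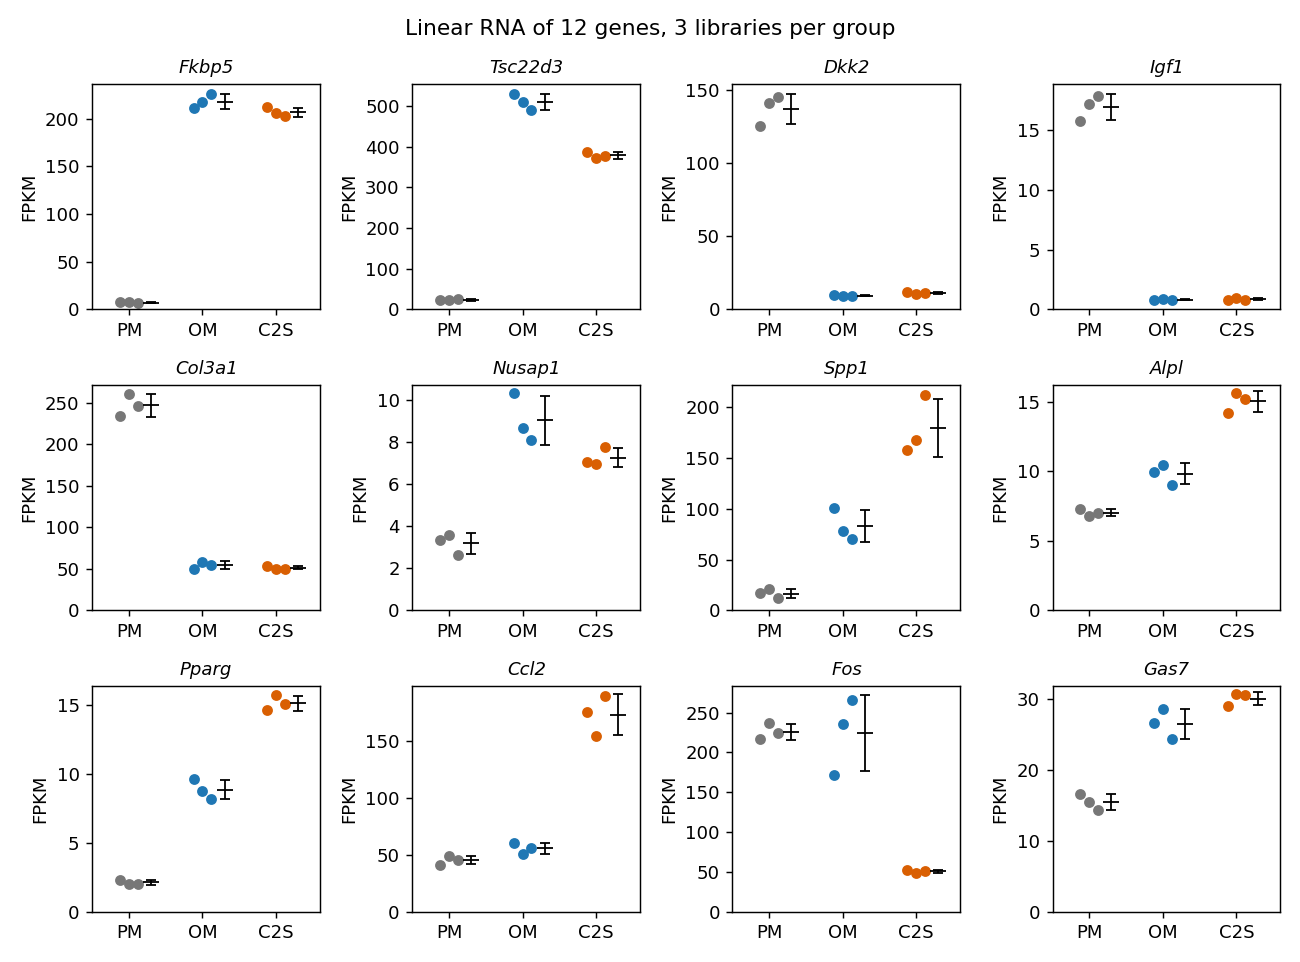
Linear RNA of 12 genes in FPKM on linear axes, with a point per library and the mean ± SD of each group beside it (n = 3). Fkbp5 lay near 7.10 in PM and between 202.5 and 226 in the OM and C2S libraries, while Fos lay near 225 in OM and 50.7 in C2S.

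Among the glucocorticoid response genes, 22 rose, 2 fell and 1 did not pass (24 adjusted over the list alone), with a median log2 change of 2.36. Camera gave the list an adjusted p of 4.5e-12, and adjusted p = 0.0302 with an estimated correlation. Besides Fkbp5 and Tsc22d3, the glutamine synthetase gene Glul (3.47 ± 0.041) and the transcription factor Klf9 (2.58 ± 0.037) rose. Of the 31 genes of the Wnt pathway list 14 were tested, and these moved down. Among them 0 rose, 13 fell and 1 did not pass (14 adjusted over the list alone). By camera the list passed at an adjusted p of 1.9e-08, and at adjusted p = 0.0318 with an estimated correlation. Its falls included Dkk2, the antagonist Dkk3 (-1.56 ± 0.051), Wisp2 (-1.78 ± 0.040) and Apcdd1 (-2.12 ± 0.052). Dkk2, Dkk3 and Apcdd1 are known as inhibitors or modulators of Wnt signalling rather than as its ligands. For extracellular matrix and collagen crosslinking, 7 rose, 24 fell and 3 did not pass (31 adjusted over the list alone). Camera's adjusted p was 7.5e-05, and the call was lost at adjusted p = 0.574 with an estimated correlation. The fibrillar collagen Col3a1 fell from 247 ± 13.7 to 54.4 ± 4.73 FPKM, and the collagen-modifying enzymes Plod2 (-2.48 ± 0.055) and P4ha1 (-1.32 ± 0.059) fell as well. In the contractile and smooth muscle list, 3 rose, 12 fell and 2 did not pass (15 adjusted over the list alone). The falls included the myosin light chain Myl9 (-1.25 ± 0.048) and the tropomyosin Tpm1 (-1.17 ± 0.047). Its camera adjusted p of 0.00121 became adjusted p = 0.419 with an estimated correlation.

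Cell cycle genes moved up together, as 30 rose, 0 fell and 5 did not pass (32 adjusted over the list alone). Among them were the replication genes Pcna (0.53 ± 0.040), Mcm7 (0.76 ± 0.056) and Ccne2 (0.84 ± 0.049). The camera adjusted p was 1.9e-08, and adjusted p = 0.574 with an estimated correlation. Of 40 cytosolic ribosomal protein genes, 33 rose, 0 fell and 7 did not pass (35 adjusted over the list alone), by small amounts such as 0.57 ± 0.051 for Rps2 and 0.37 ± 0.044 for Rpl28. These genes have many processed copies in the genome that could take reads. Camera gave them an adjusted p of 1.4e-06 (adjusted p = 0.577 with an estimated correlation). For the interferon response, 1 rose, 18 fell and 9 did not pass (19 adjusted over the list alone), with a fall of the ubiquitin-like Isg15 (-1.18 ± 0.15) and a rise of Ifit2 (0.85 ± 0.078). The list passed camera at an adjusted p of 0.00230, but adjusted p = 0.642 was found with an estimated correlation. In glycolysis and hypoxia, 4 rose, 16 fell and 2 did not pass (20 adjusted over the list alone), led by Pdk1 (-1.72 ± 0.073), Ndrg1 (-1.01 ± 0.044) and Vegfa (-1.32 ± 0.085). Here camera gave an adjusted p of 0.00133, and adjusted p = 0.139 with an estimated correlation. The unfolded protein and amino acid stress list shifted down, where 2 rose, 15 fell and 9 did not pass (17 adjusted over the list alone), including the chaperone Canx (-0.41 ± 0.044) and Edem1 (-0.62 ± 0.057). It passed at an adjusted p of 0.0201, and had adjusted p = 0.574 with an estimated correlation. Oxidative stress genes leaned up, as 12 rose, 3 fell and 10 did not pass (15 adjusted over the list alone). They included the ferritin heavy chain Fth1 (1.54 ± 0.096), a gene with many near-identical copies, and the glutathione transferase Gsta4 (0.70 ± 0.047). That list had a camera adjusted p of 0.0279, adjusted p = 0.419 with an estimated correlation and 0.0513 without OM replicate 1, in a range of 0.0185 to 0.419 over all alternatives. For lysosome and autophagy, 12 rose, 2 fell and 10 did not pass (15 adjusted over the list alone), with rises of Gpnmb (1.11 ± 0.051) and Gabarapl1 (1.16 ± 0.064). Camera's adjusted p was 0.0279, and adjusted p = 0.574 with an estimated correlation. Its call was also lost without PM replicate 1 (0.0610), PM replicate 2 (0.0695) or OM replicate 3 (0.0572), in a range of 0.0159 to 0.574.

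Lineage lists did not pass as a whole. Of the 29 osteoblast genes listed 12 were tested, of which 3 rose, 6 fell and 3 did not pass (9 adjusted over the list alone; camera adjusted p = 0.231). Falls were seen for the bone morphogenetic protein Bmp4 (-2.13 ± 0.083), the collagen Col1a2 (-1.49 ± 0.074) and the matrix protein Sparc (-0.86 ± 0.055), and a rise for the sphingomyelinase Smpd3 (1.38 ± 0.088). Adipocyte genes split, since 6 rose, 4 fell and 3 did not pass (10 adjusted over the list alone; camera adjusted p = 0.138). The fatty acid binding protein Fabp4 rose from 0.432 ± 0.0861 to 15.7 ± 1.19 FPKM and the adipogenic regulator Pparg from 2.13 ± 0.161 to 8.86 ± 0.707, while the lipoprotein lipase Lpl fell from 224 ± 12.8 to 71.2 ± 2.88. Stromal genes were divided too, as 6 rose, 12 fell and 3 did not pass (18 adjusted over the list alone; 0.231), with a rise of the transcription factor Twist2 (1.68 ± 0.044) and a fall of Prrx2 (-0.90 ± 0.045). In the inflammatory and NF-kB list, 9 rose, 7 fell and 4 did not pass (16 adjusted over the list alone; 0.658). The members included rises of the lipocalin Lcn2 (3.66 ± 0.064) and complement C3 (2.27 ± 0.097) and a fall of the chemokine Ccl7 (-2.16 ± 0.092). Beside these, the macrophage marker Lyz2, which has the near-identical copy Lyz1, fell from 4.04 ± 0.704 to 0.410 ± 0.148 FPKM. Of the other macrophage markers Cd68 fell from 3.19 ± 0.197 to 2.03 ± 0.00659, and Cd14 rose from 11.5 ± 1.01 to 27.4 ± 2.90 (all 3 adjusted over the list alone). For BMP and TGF-beta genes, 6 rose, 10 fell and 8 did not pass (16 adjusted over the list alone; 0.138), including Tgfb3 (-0.52 ± 0.050). In calcium and phosphate handling, 7 rose, 4 fell and 8 did not pass (11 adjusted over the list alone; 0.692), with Camk2d (1.22 ± 0.081) and Cacna1g (-1.25 ± 0.073). Its median was -0.043 although its mean and its test pointed up. For matrix proteases and inhibitors, 6 rose, 9 fell and 8 did not pass (15 adjusted over the list alone; 0.740), with the aggrecanase Adamts5 (2.29 ± 0.071) and the inhibitor Timp3 (-1.27 ± 0.062). The mean of 0.11 lay opposite to the median and the test. For cholesterol synthesis, 5 rose, 8 fell and 9 did not pass (13 adjusted over the list alone; 0.516), with Cyp51 (-0.82 ± 0.062) and Insig1 (0.49 ± 0.057). Among circRNA biogenesis and decay factors, 5 rose, 6 fell and 10 did not pass (11 adjusted over the list alone; 0.658), with the RNA-editing enzyme Adarb1 (0.99 ± 0.064) and G3bp2 (-0.54 ± 0.050). None of the 13 mitochondrially encoded mRNAs passed limma (0 adjusted over the list alone; 0.273). They varied strongly within OM, for example mt-Atp6 at 57.1 ± 44.1 FPKM. Of 3 tested chondrocyte genes, Sox5 (1.45 ± 0.066) and Sox9 (0.64 ± 0.10) rose, and of 3 tested endothelial genes Tek rose (0.60 ± 0.079) and Eng fell (-0.34 ± 0.074). Each of these counts was 2 adjusted over the list alone. Of the blood cell markers 1 was tested and did not pass (0 adjusted over the list alone), and Camp had a mean of 0.803 FPKM.

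**Figure D2:**
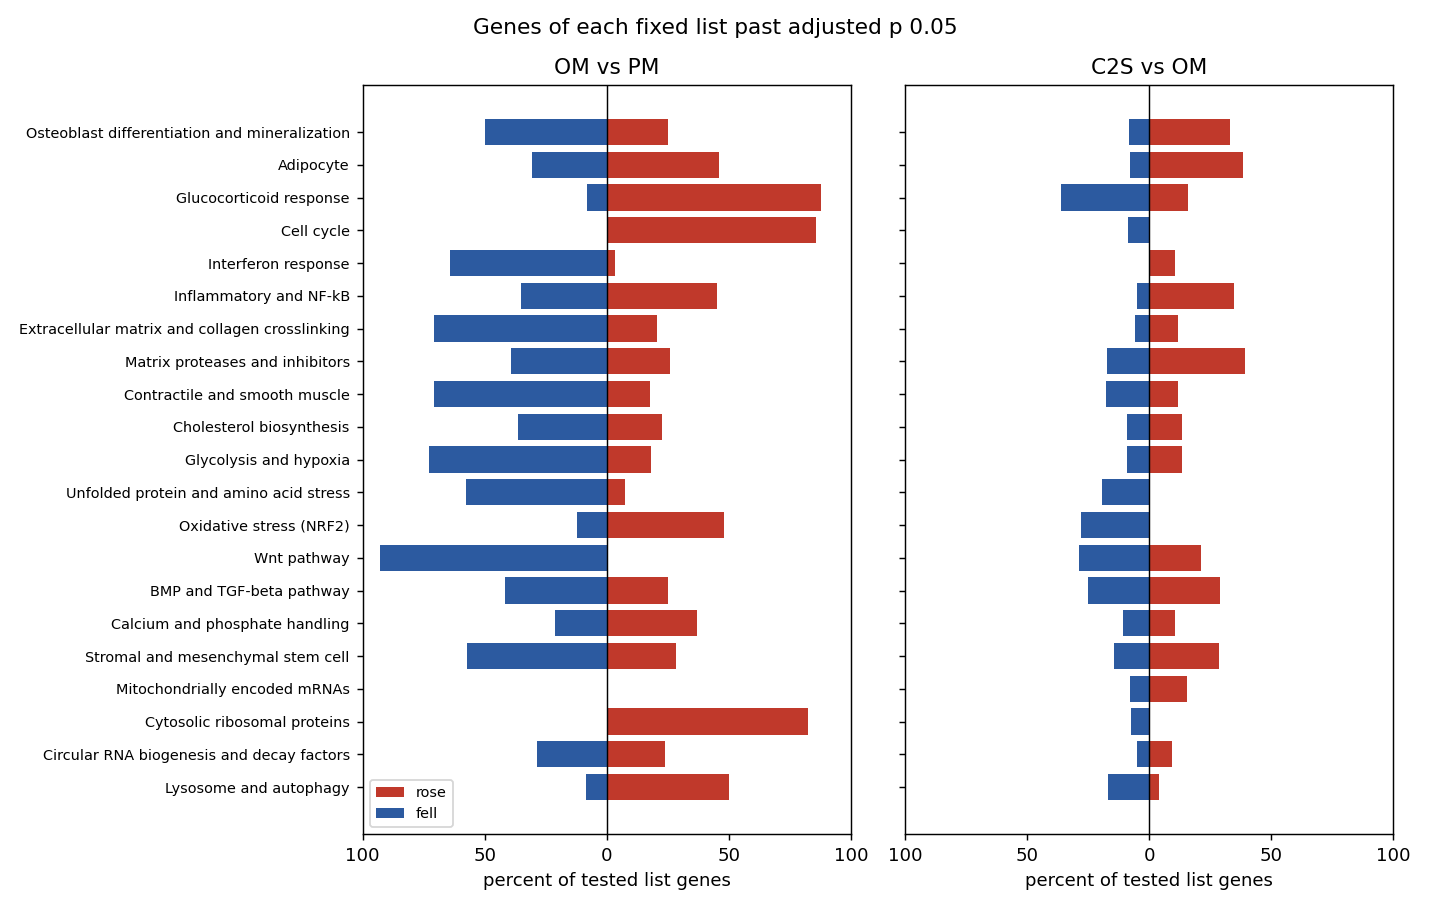
Share of the tested genes of each list, in percent, that rose (right of 0) or fell (left of 0) past an adjusted p of 0.05 in OM against PM and in C2S against OM. In OM against PM 22 glucocorticoid response genes rose and 13 Wnt genes fell.

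The comparison of C2S with OM asked what dicalcium silicate added to the osteogenic medium. The monocyte chemoattractant Ccl2 rose from 55.8 ± 4.64 FPKM in OM to 173 ± 18.0 in C2S (1.62 ± 0.092, adjusted p = 2.9e-05), the interleukin-33 receptor Il1rl1 from 17.0 ± 2.84 to 53.3 ± 5.08, and the chromatin protein Hmga2 from 47.3 ± 4.60 to 129 ± 5.19. Cd300lb (1.83 ± 0.072), Tnfaip2 (1.54 ± 0.091), the AP-1 subunit Fosl1 (1.53 ± 0.11) and Spry4 (1.48 ± 0.077), an inhibitor of receptor tyrosine kinase signalling, rose as well. So did Ifi208 (1.47 ± 0.14), of a family of similar interferon-inducible genes. Fos, an AP-1 subunit encoded by an immediate-early gene (ENSMUSG00000021250, chromosome 12, positions 85473890 to 85477273), fell from 225 ± 47.7 to 50.7 ± 2.10 FPKM (-2.10 ± 0.13, adjusted p = 5.4e-05). In PM it stood at 226 ± 10.1. Fosb (-1.71 ± 0.17), the Notch target Hes1 (-1.55 ± 0.24), Ppp1r15a (-1.43 ± 0.18), the cytokine signalling inhibitor Socs3 (-1.26 ± 0.26), Jund (-1.17 ± 0.22) and Fam107a (-0.95 ± 0.060) also fell. Several of these varied widely within OM, such as Socs3 at 33.5 ± 14.2 FPKM against 12.7 ± 0.471 in C2S. Btg2 fell by 0.97 (adjusted p = 0.0342). Its call was lost without OM replicate 2 (0.0733), OM replicate 3 (0.0794), C2S replicate 1 (0.0957), C2S replicate 2 (0.0947) or C2S replicate 3 (0.0691), and without the low-value filter (0.101), in a range of 0.00572 to 0.101. By limma 2877 of 13049 genes passed, 1380 higher and 1497 lower in C2S, with a median absolute log2 change of 0.29. A fold of at least 2 was met by 48 rises and 9 falls. The count was 1857 without C2S replicate 1, 1705 without C2S replicate 2 and 1384 without C2S replicate 3.

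Osteoblast genes that rose with C2S included the pyrophosphate transporter Ank (0.70 ± 0.064) and the tissue-nonspecific alkaline phosphatase Alpl, from 9.82 ± 0.738 to 15.005 ± 0.746 FPKM (0.57 ± 0.060). Enpp1 (0.61 ± 0.081), which generates pyrophosphate, rose too, and the osteopontin gene Spp1 went from 82.9 ± 15.7 to 179 ± 28.6 (1.11 ± 0.19). In that list 4 rose, 1 fell and 7 did not pass (6 adjusted over the list alone), and camera did not call it (adjusted p = 0.285). Gas7, the gene of the series title (ENSMUSG00000033066, chromosome 11, positions 67455437 to 67688990), stood at 15.5 ± 1.13 FPKM in PM, 26.6 ± 2.13 in OM and 30.1 ± 0.938 in C2S. It rose in OM against PM (0.74 ± 0.067, adjusted p = 1.9e-05) and in C2S against PM (0.92 ± 0.067, adjusted p = 4.3e-06), whereas C2S against OM gave 0.18 ± 0.067 and missed the threshold (adjusted p = 0.0903). Without OM replicate 2 that value was 0.233 with an adjusted p of 0.0475, and over all alternatives the adjusted p ranged from 0.0475 to 0.246.

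Camera called 2 of 21 lists in C2S against OM, both upward, and 0 with an estimated correlation. In the inflammatory and NF-kB list 7 rose, 1 fell and 12 did not pass (10 adjusted over the list alone; adjusted p = 0.0319, and adjusted p = 0.973 with an estimated correlation). The rises included Ccl2, Il1rl1, the chemokine Ccl7 (1.35 ± 0.092) and the prostaglandin E synthase Ptges (0.72 ± 0.050). Its call was lost without OM replicate 1 (0.174) or OM replicate 2 (0.0625), in a range of 0.00617 to 0.973. The macrophage marker Cd14 rose beside it from 27.4 ± 2.90 to 37.4 ± 3.31 FPKM. Lyz2 stood at 0.410 ± 0.148 and 0.549 ± 0.203, and Cd68 at 2.03 ± 0.00659 and 1.73 ± 0.141. The untested markers of that list stayed at or below 0.528 FPKM in every library, with Csf1r the highest, so the rise of Cd14 does not show macrophages. Of 3 tested macrophage genes 1 passed (1 adjusted over the list alone). For the interferon response 3 rose, 0 fell and 25 did not pass (3 adjusted over the list alone; adjusted p = 0.0183, and adjusted p = 0.973 with an estimated correlation). The rises were those of Ifi35 (0.35 ± 0.066), Isg15 (0.56 ± 0.15) and Ifi44 (0.59 ± 0.16). Among all 13049 tested genes 1380 rose, a share near that of 3 in 28. Without OM replicate 2 the interferon list had an adjusted p of 0.0687, and without C2S replicate 1 of 0.162, in a range of 2.6e-04 to 0.973. The call of Isg15 was lost without OM replicate 2 (0.0770), OM replicate 3 (0.0585), C2S replicate 1 (0.0897) or C2S replicate 3 (0.0653), in a range of 0.00524 to 0.0897. Ifi44 lost its call without each of those and without C2S replicate 2, at 0.0838, 0.0875, 0.0983, 0.0722 and 0.0559, in a range of 0.00220 to 0.0983. Without the low-value filter the adjusted p was 0.0845 for Isg15 and 0.0905 for Ifi44.

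The other lists did not pass camera in C2S against OM. Among matrix proteases and inhibitors 9 rose, 4 fell and 10 did not pass (15 adjusted over the list alone; adjusted p = 0.188). The members included rises of Mmp19 (0.86 ± 0.048), Mmp3 (1.05 ± 0.086) and the urokinase gene Plau (0.95 ± 0.069) and a fall of Adamts5 (-0.66 ± 0.071). Glucocorticoid response genes were mixed, as 4 rose, 9 fell and 12 did not pass (16 adjusted over the list alone; 0.230). Tsc22d3 was lower (-0.43 ± 0.059), and Mt2 (0.55 ± 0.076) and Hsd11b1 (0.94 ± 0.064), which regenerates active glucocorticoid, were higher. For adipocyte genes 5 rose, 1 fell and 7 did not pass (6 adjusted over the list alone; 0.268), including Pparg, which rose from 8.86 ± 0.707 to 15.1 ± 0.543 FPKM, and Lpl (0.40 ± 0.062). Stromal genes showed 6 rises and 3 falls among 21 (10 adjusted over the list alone; 0.375). Members were Vcam1 (0.56 ± 0.045) and Twist1 (0.52 ± 0.043) up and the chemokine Cxcl12 (-0.37 ± 0.038) down. BMP and TGF-beta genes went both ways, as 7 rose, 6 fell and 11 did not pass (14 adjusted over the list alone; 0.986). The BMP antagonist Grem1 (0.56 ± 0.053) was up and Id2 (-0.75 ± 0.099) was down. The list's median of -0.039 lay opposite to its mean and test. In the Wnt list 3 rose, 4 fell and 7 did not pass (8 adjusted over the list alone; 0.986), with Wisp1 up (0.41 ± 0.046) and Wisp2 down (-0.43 ± 0.040). Its mean of -0.0035 lay opposite to its median and test. Extracellular matrix genes counted 4 rises and 2 falls of 34 (6 adjusted over the list alone; 0.437), with Col6a3 (0.80 ± 0.098) and Plod2 (-0.41 ± 0.055). For contractile genes 2 rose, 3 fell and 12 did not pass (7 adjusted over the list alone; 0.986), with Cyr61 (-0.58 ± 0.083) and Lmod1 (-0.43 ± 0.083) down. Their median of 0.030 was opposite to the mean and the test. In glycolysis and hypoxia 3 rose, 2 fell and 17 did not pass (5 adjusted over the list alone; 0.986), with the hexokinase Hk2 up (0.76 ± 0.075) and Ndrg1 down (-0.36 ± 0.044). The mean of 0.018 had the opposite sign to the median and the test. Unfolded protein genes included 5 falls and 0 rises (7 adjusted over the list alone; 0.377), such as Herpud1 (-0.34 ± 0.041) and Calr (-0.35 ± 0.071). Oxidative stress genes included 7 falls and 0 rises (7 adjusted over the list alone; 0.188), such as Cat (-0.19 ± 0.037) and Tkt (-0.22 ± 0.043). In calcium and phosphate handling 2 rose, 2 fell and 15 did not pass (6 adjusted over the list alone; 0.401), with the phosphate transporter Slc20a2 up (0.42 ± 0.055) and Stim1 down (-0.33 ± 0.049). Cholesterol genes gave 3 rises and 2 falls (9 adjusted over the list alone; 0.544), with Msmo1 (0.27 ± 0.050) and Ebp (-0.32 ± 0.053). Lysosome genes gave 1 rise and 4 falls (5 adjusted over the list alone; 0.242), with Gabarapl1 (-0.34 ± 0.064) and Ctsa (-0.17 ± 0.034). Of the circRNA biogenesis and decay factors 2 rose, 1 fell and 18 did not pass (3 adjusted over the list alone; 0.401), among them the stress granule protein gene G3bp1 (0.24 ± 0.045). Cell cycle genes counted 3 falls and 0 rises (1 adjusted over the list alone; 0.377), with Ccne2 at -0.32 ± 0.049. Ribosomal protein genes had 3 falls and 0 rises (2 adjusted over the list alone; 0.188), with Rpl28 at -0.25 ± 0.044. Without OM replicate 3 the cell cycle list passed (0.0477), and without OM replicate 2 the ribosomal list did (6.3e-04), in ranges of 0.0477 to 0.973 and 6.3e-04 to 0.973. For mitochondrially encoded mRNAs 2 rose, 1 fell and 10 did not pass (3 adjusted over the list alone; 0.188), with mt-Atp6 (1.41 ± 0.43) and mt-Nd4l (1.19 ± 0.37) up and mt-Nd6 (-0.35 ± 0.076) down. Both rises lost their calls without OM replicate 1 (0.130), OM replicate 2 (0.119), C2S replicate 1 (0.0889), C2S replicate 2 (0.133) or C2S replicate 3 (0.102) for mt-Atp6, and at 0.136, 0.125, 0.0937, 0.144, 0.0877 without the same libraries for mt-Nd4l. They also missed with only the 6 libraries compared (0.0613 and 0.0622) and without the low-value filter (0.128 and 0.131), and mt-Nd4l missed under median-of-ratios scaling (0.05001) and with the other pseudocount (0.0509), in ranges of 0.00151 to 0.133 and 0.00262 to 0.144. Without OM replicate 3 the list passed (0.00176), in a range of 0.00176 to 0.973. The chondrocyte list had 1 fall among 3 tested genes, that of Col11a1 (-0.21 ± 0.064; 1 adjusted over the list alone). Its call was lost without OM replicate 2 (0.117), OM replicate 3 (0.0742), C2S replicate 1 (0.0569), C2S replicate 2 (0.151) or C2S replicate 3 (0.122), with only the 6 libraries compared (0.0720) and without the low-value filter (0.102), in a range of 0.0271 to 0.151. The endothelial list had a rise of Tek and a fall of Eng (2 adjusted over the list alone). Tek missed without C2S replicate 3 (0.0598) and with the other pseudocount (0.0526), and Eng without OM replicate 1 (0.0503), OM replicate 3 (0.0548) or C2S replicate 3 (0.0768), in ranges of 0.00267 to 0.0598 and 0.00346 to 0.0768. The blood cell gene tested did not pass (0 adjusted over the list alone). Among members that enter by their counts only, Atf3, Atp2a2, Ctgf, Dhx9, Fasn, Gla, Gstm1, Map1lc3b, Mcm7, Mvk, Nqo1, Pcna, Pnpla2, Rps2, Tpm2, Vdr and Wnt4 each lost their call without at least 1 library, with a highest adjusted p of 0.0530 to 0.131 over all alternatives.

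Across all genes, the C2S against OM changes and the OM against PM changes had a Pearson r of -0.13 and a covariance of -0.017. Both share the OM libraries. Unchanged groups simulated with that sharing, and with noise drawn independently for each gene, gave r = -0.50 and a covariance of -0.0065 with an SD of 3.7e-04. The observed covariance minus the simulated one was -0.011. Real genes vary together, so this SD is too narrow to judge that difference, and no direction is read from it. Of 1970 genes called in both comparisons, 704 moved further in the direction of OM and 1266 moved back. Tsc22d3 was among the latter, with 4.40 and then -0.43, while Pparg, with 1.66 and 0.71, and Spp1 were among the former. The shared libraries could not be split with at least 2 in each part, so part of this count may come from them.

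The comparison of C2S with PM asked what the full osteogenic treatment with silicate changed. Hp rose from 0.699 ± 0.0510 to 56.8 ± 3.14 FPKM, Mt2 from 42.3 ± 4.66 to 1399.7 ± 43.0, the flavin monooxygenase Fmo2 from 0.173 ± 0.0488 to 21.2 ± 1.11, and Spp1 from 16.7 ± 3.99 to 179 ± 28.6 (n = 3 each). Further rises were those of Sult1a1 (5.83 ± 0.068), Fkbp5 (4.68 ± 0.043), Dpep1 (4.41 ± 0.052), Ndrg2 (4.09 ± 0.055) and Tsc22d3 (3.98 ± 0.059). Scg2 fell from 623 ± 39.9 to 35.5 ± 3.08 FPKM, and Ccl8 (-4.20 ± 0.14), Syt13 (-3.79 ± 0.075), Qpct (-3.58 ± 0.11), Dkk2 (-3.52 ± 0.062), Penk (-3.44 ± 0.089), Igf1 (-3.29 ± 0.065) and the myocilin gene Myoc (-3.22 ± 0.076) fell too. By limma 7311 genes passed, 3605 higher and 3706 lower in C2S, of which 505 and 358 met a fold of at least 2. Between OM against PM and C2S against PM, 5537 genes were called in both in the same direction (2659 up and 2878 down) and 77 in opposite directions. Independent lists of these sizes would share 979 up and 1025 down. Simulated unchanged groups sharing the PM libraries made no calls to share (a mean overlap of 0), which says nothing about the overlap. Their fold changes had a mean r of 0.494 and a mean of 66.6% with the same sign, with a covariance of 0.0065, against 0.905, 82.9% and 0.275 observed. With a fold of at least 2 in both, 603 were shared, and because the PM libraries could not be split, part of the overlap may come from them.

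Camera called 8 lists in C2S against PM. In the glucocorticoid list 20 rose, 2 fell and 3 did not pass (22 adjusted over the list alone; adjusted p = 3.9e-11), and in the Wnt list 0 rose, 12 fell and 2 did not pass (13 adjusted over the list alone; 1.5e-07). These calls held at adjusted p = 0.0372 and 0.0426 with an estimated correlation. Cell cycle genes gave 31 rises of 35 (32 adjusted over the list alone; 1.5e-07), with Nusap1 at 0.99 ± 0.10. Ribosomal protein genes gave 27 rises of 40 (30 adjusted over the list alone; 7.8e-05), with Rps18 at 0.51 ± 0.073. These lists lost their calls, at adjusted p = 0.511 and 0.660 with an estimated correlation. Extracellular matrix genes counted 24 falls and 7 rises (31 adjusted over the list alone; 2.2e-04), with Plod2 at -2.89 ± 0.055. Contractile genes counted 13 falls and 4 rises (17 adjusted over the list alone; 8.7e-04), with Cyr61 at -1.81 ± 0.083. Both calls were lost, at adjusted p = 0.511 and 0.439 with an estimated correlation. Glycolysis and hypoxia had 15 falls and 5 rises (20 adjusted over the list alone; 0.00646), with Ndrg1 at -1.37 ± 0.044. The unfolded protein list had 18 falls and 1 rise (20 adjusted over the list alone; 0.00183), with Atf4 at -0.45 ± 0.052. Their calls ended as well, at adjusted p = 0.245 and 0.511 with an estimated correlation. The osteoblast list did not pass (0.763), and in it 5 rose, 5 fell and 2 did not pass (11 adjusted over the list alone). Adipocyte genes, of which 7 rose, 3 fell and 3 did not pass (10 adjusted over the list alone), missed at 0.0566. They passed without C2S replicate 1 (0.0338), C2S replicate 3 (0.0445) or with the filter of 30 reads (0.0480), in a range of 0.0338 to 0.438. Mitochondrially encoded mRNAs (0.0566; 8 rose, 1 fell and 4 did not pass, 9 adjusted over the list alone) passed without PM replicate 1 (0.0238), C2S replicate 1 (0.0338) or C2S replicate 3 (0.0445), and with only the 6 libraries compared (0.00909) or the filter of 30 reads (0.0480), in a range of 0.00909 to 0.660. The interferon list (0.175; 2 rose, 10 fell and 16 did not pass, 8 adjusted over the list alone) passed without PM replicate 3 (0.0133) or C2S replicate 1 (0.0338), in a range of 0.0133 to 0.868. The stromal list did not pass (0.980), and its median of -0.10 lay opposite to its mean and test.

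CircRNAs are covalently closed transcripts read out at back-splice junctions, and in OM against PM several appeared that have no value in all PM libraries and are given as 0 here. A 0 is no proof of absence, since 34 of 2461 entries had no value although both other libraries of their group held at least 10 reads each. Groups with 2 unlisted libraries do not enter that count, such as PM for circ_233, with 0, 0 and 158 reads. Of the 29 circRNAs with such entries 21 had ends in 2 genes, against 121 of all 2898 tested. For circRNAs of that kind, such as circ_469 below, a 0 is therefore less certain. The Fkbp5 circRNA circ_1228 (chromosome 17, positions 28428352 to 28441053, exonic) was at 0 in PM and at 2095 ± 340.2 RPM in OM (adjusted p = 1.2e-07), resting on 34 to 50 reads per OM library. Circ_469 (chromosome 7, positions 126675049 to 126688685), with ends in exons of Sult1a1 and its copy Gm6939, was at 0 in PM and 3639 ± 269 in OM (adjusted p = 7.6e-10), the intergenic circ_1164 (chromosome 10, positions 47474521 to 47475428) at 0 and 1166 ± 355, and circ_174 of Ehbp1 (chromosome 11, positions 22169035 to 22173006) at 0 and 590.4 ± 123. Among exonic circRNAs of the glutamate receptor gene Grik2, circ_2440 (chromosome 10, positions 49523682 to 49578302) rose from 212 ± 185 to 1831 ± 138 RPM (2.83 ± 0.40) and circ_689 (chromosome 10, positions 49523682 to 49535499) from 176 ± 172 to 1545 ± 38.8 (2.74 ± 0.39). In PM they held 4, 5 and 0 reads and 0, 5 and 3 reads, so the size of both rises rests on few reads. Circ_2755 (chromosome 3, positions 144807316 to 144828136), whose ends lie in the similar genes Clca3a2 and Clca3b, fell from 2563 ± 339.7 to 405 ± 61.9 RPM (-2.37 ± 0.22, adjusted p = 3.8e-05). Falls with less secure calls were circ_1560 of Dscam (chromosome 16, positions 97038898 to 97056765), at -2.09 ± 0.40, and circ_2799 of Gas2 (chromosome 7, positions 51887912 to 51897372), at -2.86 ± 0.60. The first lost its call without PM replicate 1 (0.0516), PM replicate 2 (0.0606) or PM replicate 3 (0.0736), in a range of 4.2e-04 to 0.0736. The second lost it without PM replicate 1 (0.0758), PM replicate 2 (0.139) or OM replicate 1 (0.0897) and by voom (0.0889), in a range of 1.0e-07 to 0.139. Other falls came from circ_1848 of Col24a1 (chromosome 3, positions 145313991 to 145315417), at -2.29 ± 0.52, circ_10829 with ends in Lyz2 and Lyz1 (chromosome 10, positions 117280641 to 117289197), at -2.15 ± 0.45, and circ_5536 of Rnf150 (chromosome 8, positions 83036025 to 83042782), at -2.13 ± 0.48. They rested on 4 to 12 reads per PM library (adjusted p = 0.0455, 0.0259 and 0.0429). With only the 6 libraries compared their adjusted p was 0.0641 each. Circ_1848 lost its call without PM replicate 1 (0.0831), PM replicate 2 (0.150), PM replicate 3 (0.138), OM replicate 2 (0.108) or OM replicate 3 (0.110), and circ_5536 without the same libraries (0.0959, 0.0813, 0.0773, 0.144, 0.144). Circ_10829 lost it without OM replicate 1 (0.101), OM replicate 2 (0.0897) or OM replicate 3 (0.0980). When circRNA reads were scaled by linear reads circ_1848 (0.0740) and circ_5536 (0.0749) missed too, as did circ_1848 under median-of-ratios scaling (0.0555). The ranges were 0.00206 to 0.150, 0.00278 to 0.101 and 0.00860 to 0.144. By limma 45 of 2898 circRNAs passed, 21 higher and 24 lower in OM, and 36 and 8 when circRNA reads were scaled by linear reads. The count was 28 without PM replicate 1, 17 without PM replicate 2, 28 with only the 6 libraries compared and 79 without the low-value filter.

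**Figure D3:**
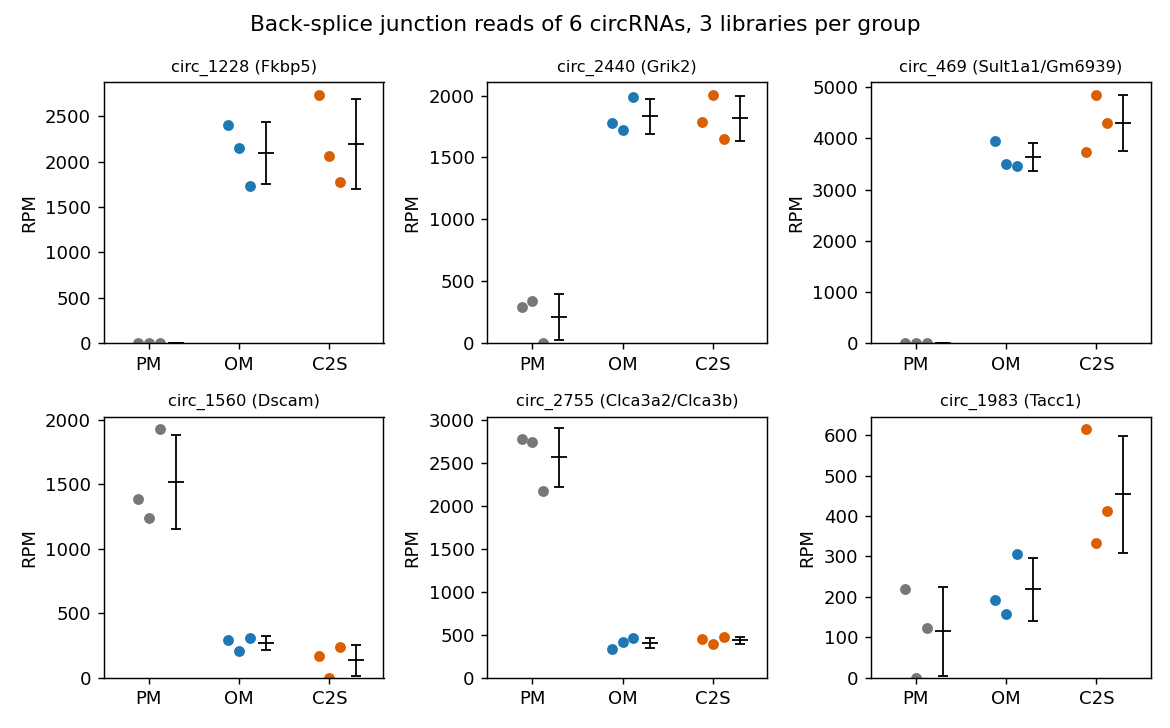
Back-splice junction RPM of 6 circRNAs, with a point per library and the mean ± SD of each group beside it (n = 3). Circ_1228 of Fkbp5 was listed at 0 in the PM libraries, and circ_1983 averaged 114 RPM in PM, 218 in OM and 454 in C2S.

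In C2S against OM, the circRNA listed as circ_1983 did not pass. It was matched to the series title by this identifier alone, as the title gives no coordinates, and whether it is the same circRNA is open. The entry is listed as an exonic circRNA of Tacc1 on the minus strand of chromosome 8, positions 25159645 to 25177994, spanning 18350 bases. Position 25177994 is an annotated exon end, but 25159645 is not an annotated exon start, unlike the starts of 96.6% of listed exonic circRNAs. The reads of circ_1983 were 3, 0 and 2 in PM, 4, 3 and 6 in OM and 11, 6 and 7 in C2S, or 114 ± 109.9, 218 ± 77.7 and 454 ± 144 RPM. The log2 fold changes were 0.77 ± 0.46 for C2S against OM (adjusted p = 0.901), 0.66 ± 0.46 for OM against PM (0.549) and 1.43 ± 0.46 for C2S against PM (0.171). The simulated changes, of which 44.8% of the 2-fold ones were recovered, were placed in circRNAs with more reads on average than circ_1983. They do not measure what was detectable at its reads. The circRNAs of Gas7, circ_6255 (chromosome 11, positions 67603108 to 67643366) and circ_7824 (chromosome 11, positions 67643281 to 67662166), were each listed with 2 reads in 1 OM library and were not tested. Limma called 0 circRNAs, with 151 at an unadjusted p under 0.05, voom called 0, and limma without the low-value filter called 16, 11 higher and 5 lower in C2S. The smallest p-values among tested circRNAs, none past the threshold, included that of circ_5779, with ends in Cyp4f16 and Cyp4f37 (chromosome 17, positions 32546630 to 32631365). It was listed at 425 ± 221 RPM in OM and at 0 in C2S (adjusted p = 0.504, and 0.0275 without the low-value filter, in a range of 0.0275 to 0.926). The others were circ_477, with ends in Mmp3 and Mmp10 (chromosome 9, positions 7447522 to 7503629), at 102 ± 105 RPM in OM and 568 ± 42.4 in C2S, circ_1967 of Dyrk1a (chromosome 16, positions 94659497 to 94677592) and circ_2132 (chromosome 4, positions 89380333 to 89399872).

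In C2S against PM, circ_469 (4301 ± 555 RPM in C2S), circ_1228 (2190.4 ± 495) and circ_1164 (931 ± 141) were again listed at 0 in PM and passed (adjusted p = 4.1e-10, 1.1e-07 and 6.2e-05). Circ_2440 rose by 2.81 ± 0.40 and circ_689 by 2.53 ± 0.39, while circ_1560 (-2.85 ± 0.40) and circ_2755 (-2.28 ± 0.22) fell. Circ_1804 of Mndal (chromosome 1, positions 173874351 to 173935177), of a family of similar genes, was at 0 in PM and at 2609 ± 267 RPM in C2S (adjusted p = 0.00812). It is listed as intronic, although both ends lie at annotated exon boundaries, and position 173935177 also lies within Ifi203. In OM circ_1804 held 49, 0 and 35 reads, so the junction can go unlisted beside libraries with many reads. Its 0 in PM may be of the same kind. Its call was lost without C2S replicate 2 (0.0615) and by voom (0.127), in a range of 4.4e-27 to 0.127. Further falls were those of circ_2491 with ends in Serpina3h and Serpina3i (chromosome 12, positions 104251472 to 104265712), at -2.47 ± 0.48, circ_5817 with ends in Pbld2 and Pbld1 (chromosome 10, positions 63047468 to 63061701), at -2.20 ± 0.42, circ_5536 (-2.43 ± 0.48) and circ_10829 (-2.15 ± 0.45). Circ_2491 held 6, 9 and 0 reads in the C2S libraries, so the entry at 0 adds to the size of its fall. It lost its call without PM replicate 1 (0.0542) or PM replicate 2 (0.0624), and with only the 6 libraries (0.0749), in a range of 5.0e-08 to 0.0749. Circ_5817 lost it without PM replicate 2 (0.0624) or PM replicate 3 (0.0506), and with only the 6 libraries (0.0501), in a range of 0.00349 to 0.0624. Without C2S replicates 1, 2 and 3 in turn the adjusted p was 0.0566, 0.0683 and 0.0578 for circ_5536 and 0.0789, 0.0853 and 0.0768 for circ_10829, which also missed with only the 6 libraries (0.0688). The ranges were 0.00117 to 0.0683 and 0.00475 to 0.0853. By limma 48 circRNAs passed, 27 higher and 21 lower in C2S, and 30 and 14 when circRNA reads were scaled by linear reads. Their number was 29 without PM replicate 2, 31 without C2S replicate 1, 23 without C2S replicate 2, 29 without C2S replicate 3, 23 with only the 6 libraries compared and 88 without the low-value filter.

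Called circRNAs moved with their host genes in the comparisons against PM. Of 33 called circRNAs in OM against PM with a tested host gene, 33 had a host that passed in the same direction, as did 35 of 36 in C2S against PM. Among all 13049 linear genes 7151 and 7311 passed in these comparisons, in either direction. The share over the hosts of all tested circRNAs was not taken. For circ_1228 the host Fkbp5 rose by 4.76. Across 2690 circRNAs, which are not independent replicates, Pearson's r between circRNA and host changes was 0.434 in OM against PM (Spearman's rho 0.357), 0.0728 in C2S against OM (0.0579) and 0.423 in C2S against PM (0.341). The bootstrap SDs of r were 0.029, 0.021 and 0.025. With at least 10 reads in 3 libraries r was 0.717 and 0.705 in the comparisons against PM. Relative to the host, limma called 12 circRNAs in OM against PM, 3 higher and 9 lower, 0 in C2S against OM (168 at an unadjusted p under 0.05) and 8 in C2S against PM, 1 higher and 7 lower. Of the 9 lower, 5 were circRNAs of Fkbp5, such as circ_2, whose own change of 0.73 did not pass (adjusted p = 0.461). Its change relative to the host was -4.02 ± 0.47. The change relative to the host was -2.73 for circ_2318 of the versican gene Vcan (adjusted p = 0.0139) and -2.76 for circ_4112 of Zbtb16 (adjusted p = 0.0246). These 3 circRNAs were chosen after their values were seen. These calls rested on the pseudocount and on low reads, since a pseudocount 5 times smaller gave 0 calls in either comparison, and the filter of 10 reads gave 1 call in each. That call was among the 12 in OM against PM and not among the 8 in C2S against PM. In OM against PM the count was 6, 6 and 7 without PM replicates 1, 2 and 3, and 3, 6 and 5 without OM replicates 1, 2 and 3. In C2S against PM it was 5 without PM replicate 2, 13 without PM replicate 3, 3 without C2S replicate 1 and 4 without C2S replicate 3. The change of circ_1983 relative to Tacc1 did not pass in any comparison, for example 1.17 in C2S against PM (adjusted p = 0.368).

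**Figure D4:**
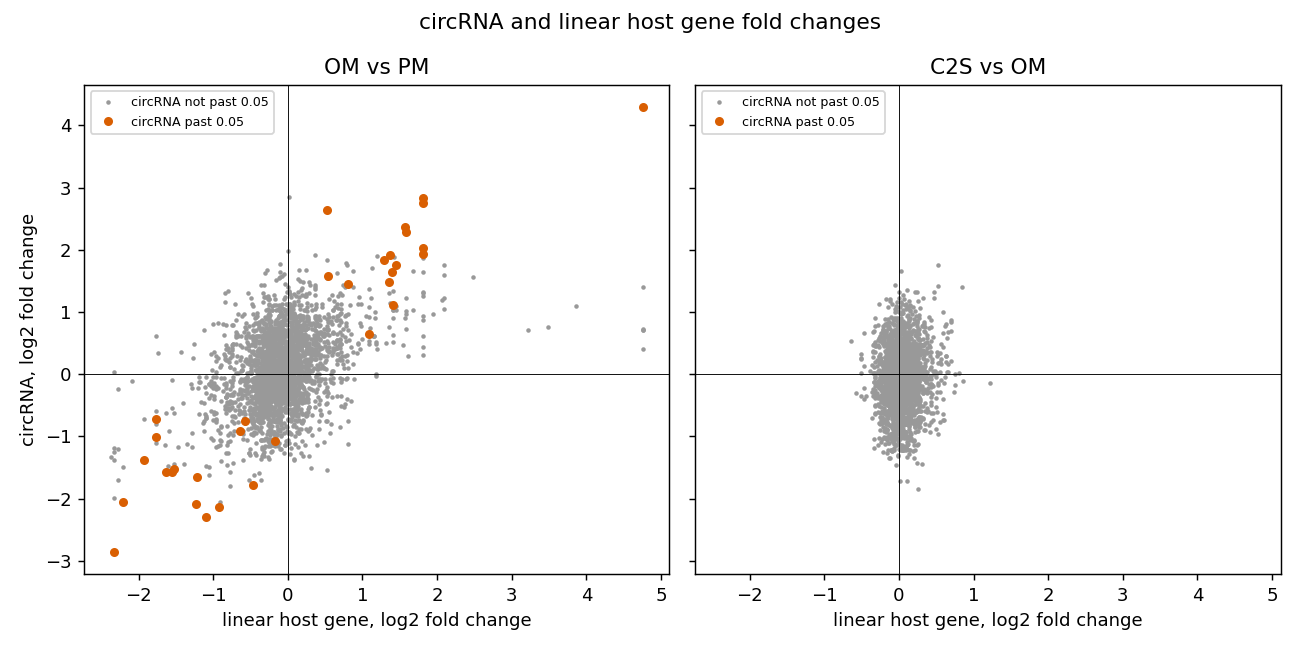
Log2 fold change of each circRNA against that of its host gene, for OM against PM and C2S against OM, with circRNAs past an adjusted p of 0.05 in orange. Pearson's r was 0.434 in the first and 0.0728 in the second.

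Total circRNA junction reads per 1000000 linear reads were 462 ± 72.5 in PM, 572 ± 75.4 in OM and 528 ± 8.41 in C2S (n = 3 each). Two-sided exact permutation tests gave p = 0.2 for OM against PM and 0.4 for each of the others (adjusted 0.4 for each), where 0.1 is the smallest p possible. After thinning to 12401 reads, 2135 ± 145 circRNAs were detected in PM, 2572 ± 79.7 in OM and 2358 ± 38.2 in C2S, with an exact permutation p of 0.1 for each pair. Requiring at least 2 reads after thinning gave 2012 ± 44.1, 2014 ± 28.1 and 1978 ± 26.7, and the difference between C2S and PM changed sign, from 222 to -34.1. As the files hold no circRNA with 1 read, the first count still varies with depth, and no order of the groups was read from it.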

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

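Of the alternatives below, voom on the recovered reads and the tests without circRNAs whose ends lie in 2 genes or unlisted beside many reads were chosen after the result was seen. The negative binomial alternative was not run. The cause of the changes below was not tested unless the setting itself removes libraries, genes or reads. Requiring a fold of at least 2 left 776, 57 and 863 linear genes in OM against PM, C2S against OM and C2S against PM, and 603 shared between the comparisons against PM. Without the low-value filter limma called 79, 16 and 88 circRNAs, and with only the 6 libraries compared 28 against PM for OM and 23 for C2S. Without the 29 circRNAs unlisted in a library beside many reads in its group, limma called 56, 0 and 60, sharing 45, 0 and 47 calls with the full set. With an estimated correlation camera called 2, 0 and 2 lists. Relative to the host gene, a pseudocount 5 times smaller left 0 circRNAs in OM against PM and 0 in C2S against PM, and the stricter read filter gave 1 in each, which was among the original calls in OM against PM only. That filter raised the circRNA and host correlations to 0.717, 0.106 and 0.705. Among genes called in OM against PM the covariance of the fold changes was -0.0271. Requiring 2 or more reads turned the difference in detected circRNAs between C2S and PM to -34.1.

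Leaving out 1 library at a time gave ranges of 1384 to 2312 linear genes in C2S against OM, 17 to 49 and 23 to 47 circRNAs in OM and C2S against PM, 1 to 4 lists in C2S against OM, and 3 to 7 and 3 to 13 circRNAs relative to the host in OM and C2S against PM. The circRNA and host correlations ranged over 0.394 to 0.442 and 0.379 to 0.411 in the same comparisons, and the covariance from -0.0254 to -0.0141.

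Lists whose direction turned were past the threshold in neither setting. In OM against PM these were calcium and phosphate handling with the stricter read filter (adjusted p 0.996) and with libraries left out (0.700 to 0.972), and matrix proteases with libraries left out (0.645 to 0.923). In C2S against OM the contractile list turned under median-of-ratios scaling (0.958) and with only the 6 libraries (0.894), and glycolysis did so at 0.958 and 0.894. The BMP and TGF-beta list turned with the stricter filter (0.979). With libraries left out, the ranges were 0.825 to 0.977 for contractile, 0.888 to 0.996 for glycolysis, 0.825 to 0.977 for BMP and TGF-beta, and 0.825 to 0.997 for Wnt genes. In C2S against PM the stromal list turned with the stricter filter (0.877) and with the 6 libraries (0.998), and circRNA factors with libraries left out (0.661 to 0.955).

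Replicate numbers were not taken to pair the samples, since not every pair with the same number had deviations from group means that correlated over 0.1. For linear genes these were -0.0243, 0.395 and 0.374 between OM and PM, 0.0841, 0.246 and 0.0882 between C2S and OM, and -0.0921 between C2S 1 and PM 1. Every library correlated best with its own number between C2S and OM, a hint from the data and not the design, but not in the comparisons against PM. With the number as a block, camera called 1 list in C2S against OM, with inflammatory genes at 0.0991, and 6 circRNAs changed relative to the host in OM against PM. The contractile (0.975) and BMP (0.9997) lists turned direction under this block. It changed no other count of calls by over 1.5 times. Of the features printed with their fold change, it ended the calls of mt-Atp6 (0.0541), mt-Nd4l (0.0635) and Col11a1 (0.0671) in C2S against OM, of circ_1848 (0.0650), circ_10829 (0.0632) and circ_5536 (0.0766) in OM against PM, and of circ_10829 in C2S against PM (0.0585).

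Among named genes, 1644 leave-out tests kept direction and side of the threshold, 1 newly passed and the rest missed it, and by voom 298 of 298 kept both. Named circRNAs kept both in 141 leave-out tests and missed in 30. Lists kept both in 347, missed in 8, newly passed in 10 and turned in 13. A median of 3 reads per listed circRNA limits the circRNA results. In C2S against OM 44.8% of simulated 2-fold changes were recovered, and these were placed only in circRNAs above a minimum of mean reads.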

Other observations

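The immediate-early list and its genes named here, the tests of handling at harvest and of a bias behind 0.5 of the fall, the splits of the libraries and the test without circRNAs joining 2 genes were chosen after the results were seen. Immediate-early genes, which respond to stimuli within minutes to hours, were listed from general knowledge after Fos and Fosb had been seen to fall in C2S against OM. Of 28 tested, 15 fell and 3 rose, and 22 were lower in C2S. Jun fell from 52.5 ± 9.49 to 32.6 ± 1.01 FPKM, the mRNA decay factor Zfp36 from 67.5 ± 15.4 to 36.95 ± 0.546, and the nuclear receptor Nr4a2 from 4.198 ± 1.16 to 2.198 ± 0.043 (n = 3 each, limma adjusted p = 0.00472, 0.00445 and 0.0141). Junb stood at 215 ± 78.4 and 120.0 ± 16.1 and missed the threshold (adjusted p = 0.0636). Arc, Egr3 and Klf10 rose, by 0.45, 0.64 and 0.32 on the log2 scale. In OM against PM 7 of the list rose and 4 fell, and in C2S against PM 13 fell and 7 rose.

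The median log2 change of the list in C2S against OM was -0.48 with a bootstrap SE of 0.14. Genes matched on GC content, transcript length and level had a median of -0.0457, and the 28 matched medians lay between -0.122 and 0.0275. A bias of that kind behind at least 0.5 of the fall needs a matched median at or below 0.5 of the list's, and it lay 0.193 above that, with a bootstrap SE of 0.0742. The gap was under 2 SE of the list's own median, the spread fixed beforehand, which is wider than that of the difference compared. By the spread fixed beforehand the test therefore cannot decide. By the spread of the difference, chosen afterwards, the values argue against a bias behind at least 0.5 of the fall. A smaller part was not excluded.

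Handling at harvest, such as time between opening the dish and lysis, may move these genes and stays open. Within groups their SD on log2(FPKM + 1) was a median of 2.26 times that of genes matched on level alone. The wide spread in OM had been seen before, so this ratio decides nothing. Some members also rose with the replicate number in every group. Junb stood at 121, 183 and 193 FPKM in PM, 140, 208 and 297 in OM and 108, 113 and 138 in C2S. Others did not, such as Fosb at 50.6, 48.7 and 35.5 in PM. Members of each kind were not counted, and what this order reflects was not tested. For Fos the SD was 47.7 FPKM in OM and 2.10 in C2S. A response to the silicate itself also remains open, because handling and treatment cannot be told apart when the labels give no harvest order.

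Of the 2898 tested circRNAs, 121 (4.18%) had their ends in 2 different genes. They made up 10 of 45 calls in OM against PM (22.2%) and 11 of 48 in C2S against PM (22.9%), Fisher's exact p = 1.03e-05 and 2.60e-06. Fisher's test takes circRNAs as independent, although the 121 came from 81 gene pairs. Reads per circRNA were not matched, so a difference in reads may be part of this excess. Of 81 joined gene pairs, 69 (85.2%, exact binomial 95% interval 75.6% to 92.1%) had transcripts alike over at least 50 bases at 80% identity or more, against 24 of 1000 neighbouring pairs on the same strand (2.4%). Reads placed between paralogs are therefore a candidate source of these junctions, of which circ_469 (Sult1a1 and Gm6939) and circ_2755 (Clca3a2 and Clca3b) are examples. Such a junction could then follow the level of the linear mRNA, as circ_469 did with Sult1a1. Read-through transcripts or true circles across tandem genes were not tested, and limma without these circRNAs called 39, 0 and 36 in OM against PM, C2S against OM and C2S against PM.

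The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For linear genes the real split gave 7151 in OM against PM, 2877 in C2S against OM and 7311 in C2S against PM, and the highest other split 0 in each, so 1 of 10 was as large. For circRNAs the real and highest other values were 45 and 2, 0 and 3, and 48 and 1, and 1, 10 and 1 splits were as large. Relative to the host they were 12 and 1, 0 and 0, and 8 and 0, with 1, 10 and 1 splits as large. For lists they were 11 and 9, 2 and 5, and 8 and 8, with 1, 8 and 2 splits as large. Counts of lists near or above the real ones thus came from other splits in all 3 comparisons. The 5 in C2S against OM came from OM replicates 1 and 2 with C2S replicate 2 against the rest. The source of these counts was not tested.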
